A study of Mus musculus with 18 samples.

How the data were processed

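Total RNA from the kidney cortex of C57Bl/6 mice was sequenced after ribosomal depletion in 18 libraries. They form 6 groups of 3 libraries by genotype (Klf6fl/fl or Klf6PTKO) and treatment. The treatments were the DMSO vehicle, aristolochic acid I (AAI) for 3 weeks, and the same course of AAI with a further 3 weeks left for remodeling, which the sample titles call 6 weeks. Groups were taken from the sample labels alone. Each genotype has 1 DMSO group, which serves as the control at both times. The labels do not state the week at which each DMSO kidney was taken, nor that the libraries of a group come from separate animals.

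The deposited table holds values in CPM (read counts scaled to a common library total) for 24062 gene symbols in the 18 libraries. Per the submitters' processing notes, bcl2fastq 2.19, kallisto and the mm10 genome were used, and the values are CPM made by the authors. Each value times the library's inferred read total was tested for being a whole number. All 433116 values (100%) lay within 0.01 read of a whole number, so read counts were recovered for the methods that need them. The recovered totals ran from 11722625 to 27213219 reads per library. A value of 0 in 1 library allows a level of up to 3 reads of that library's total, and this limit covers counting error only. The table holds 27 symbols that had been turned into calendar dates, which were kept as unnamed genes. Of the gene symbols, 22683 matched 1 gene of GENCODE release M21, which supplied positions. The mitochondrially encoded genes were not in the table and were not analysed here.

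Genes with at least 1 CPM in at least 3 libraries were tested, which left 14604. The log2 of CPM plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with 6 group means over all 18 libraries, 12 residual degrees of freedom and a variance trend in the empirical Bayes step. Log2 fold changes in the text are on this log2(CPM + 1) scale. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counted as a change. In all, 11 comparisons were made. They were AAI against DMSO within each genotype at each time, the genotypes against each other within each treatment, the later against the earlier AAI time within each genotype, and the genotype by AAI interaction at each time. Confidence intervals are at 95%. For Klf6 and for summary scores an exact permutation test is also given. With 3 libraries against 3 its smallest p is 0.1.

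Before the data were examined, 39 gene lists (pathways, cell type markers and controls) were fixed, and those with at least 5 tested members were tested with camera in limma at its preset correlation of 0.01, adjusted over lists. The branched-chain amino acid list follows a pathway that the study took up partly on these samples. The size of the AAI response was summarised over the 500 genes with the largest average response of both genotypes, so that the choice of genes does not use the genotype difference, and tested by an exact permutation of genotype labels within treatments.

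The genes named in the text follow a rule also fixed before the data were examined. It takes Klf6. It takes up to 5 genes higher and 5 lower with the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, and for interactions without the overlap condition. Unnamed gene models, mitochondrially encoded genes and immunoglobulin or T cell receptor segments were left out. It takes, for each list described, up to 3 members with the smallest adjusted p among those that passed, or else the member with the highest mean CPM. It takes Havcr1, Lcn2, Slc5a2 and Bckdhb as fixed examples. Not every gene the rule gives is printed.

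Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 CPM, median-of-ratios scaling, quantile normalization, a fit on the compared groups alone, the replicate number as a block, a fold minimum of 1 on the log2 scale, no variance trend, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, an estimated correlation between the genes of a list, 200 or 2000 response genes, and leaving out each library in turn. edgeR and DESeq2 were kept as alternatives because the deposited values are CPM. After the data were seen, 3 alternatives were added, which were fry (limma) in place of camera, thinning all libraries to the reads of the shallowest (11722625), and leaving out 3 libraries that stood apart within their groups. The fit was tested on simulated data built from these libraries. In the comparison of AAI at 3 weeks with DMSO it recovered 72% of genes changed 2-fold and 96% of those changed 4-fold, and for the interaction at 3 weeks 57% and 90%. The simulation changed 100 of 13319 genes at each fold, up and down alike, with the same spread of a gene in every group. It therefore cannot show how the fit behaves when most genes change or when groups vary unequally.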

Results

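RNA levels were measured by total RNA sequencing of mouse kidney cortex in 18 libraries, 3 in each of 6 groups. Both genotypes are C57Bl/6 mice. Klf6fl/fl (fl/fl) carries floxed alleles of Klf6, which encodes a zinc finger transcription factor of the Krüppel-like family. Klf6PTKO is the label of the knockout in the proximal tubule, the segment that reabsorbs most of the filtered solutes, and its libraries are called "labelled PTKO" here. Each genotype was given the DMSO vehicle or AAI, a plant toxin that injures the proximal tubule. AAI kidneys were taken at the end of 3 weeks of treatment (3-week libraries) or after 3 more weeks of remodeling (6-week libraries). Values are CPM as deposited, with the mean ± SD of 3 libraries, and fold changes are limma estimates on the log2(CPM + 1) scale with Benjamini-Hochberg adjusted p. Reads per library ran from 16516093 to 20787996 in the DMSO groups and from 21325952 to 27213219 in the 3-week groups. At 6 weeks they ran from 11722625 to 20063456 in fl/fl and from 19011323 to 19552233 in the libraries labelled PTKO. The p-values measure the spread between these libraries, since the labels do not say whether they come from separate animals. That spread was pooled over all 6 groups, which did not vary alike. The log2 values of libraries within a group correlated at 0.988 to 0.9952 under DMSO. In the 6-week libraries labelled PTKO they correlated at 0.9703 to 0.9914. The limma p-values for the more variable groups can therefore be too small.

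Klf6 (ENSMUSG00000000078.7, a protein-coding gene on the plus strand of mm10 chromosome 13, 5861482 to 5870394) is the gene the genotype names. It was present at similar levels in both genotypes under every treatment. Under DMSO its level was 39.7, 39.2 and 42.3 CPM in the fl/fl libraries and 40.2, 43.2 and 56.7 CPM in those labelled PTKO. At 3 weeks of AAI the levels were 308, 273 and 256 CPM in fl/fl and 310, 280 and 229 CPM in the libraries labelled PTKO. The 6-week levels were 284, 201 and 270 CPM in fl/fl and 228, 254 and 370 CPM in the libraries labelled PTKO. The difference between genotypes (labelled PTKO minus fl/fl) was 0.19 under DMSO (95% interval -0.19 to 0.57, exact permutation p = 0.2). It was -0.04 at 3 weeks (-0.43 to 0.34, exact permutation p = 1) and 0.16 at 6 weeks (-0.23 to 0.54, exact permutation p = 0.6). Whole cortex holds Klf6 transcripts of all its cell types, and the table counts no exon apart, so the values do not check the genotype label. AAI raised Klf6 in both genotypes. In fl/fl it rose by 2.76 ± 0.18 (SE) at 3 weeks (adjusted p = 1.75e-09) and 2.60 ± 0.18 at 6 weeks (adjusted p = 6.48e-09). In the libraries labelled PTKO the rise was 2.53 at 3 weeks (adjusted p = 8.98e-09) and 2.56 at 6 weeks (adjusted p = 1.94e-08). The exact permutation p was 0.1 for each of these 4 comparisons, the smallest that 3 libraries against 3 allow.

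**Figure D1:**
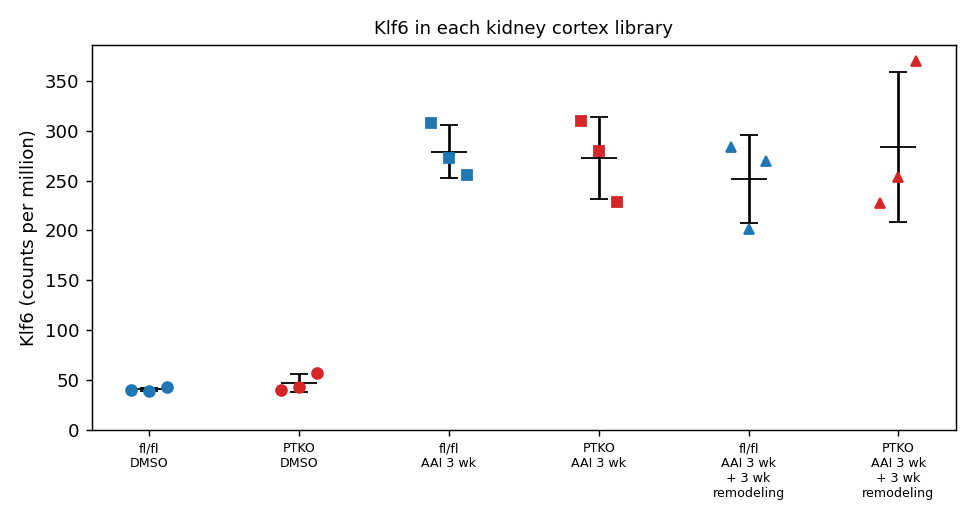
Klf6 level (CPM, vertical axis) in each library of the 6 groups, with fl/fl in blue and the libraries labelled PTKO in red; points are libraries and the bars are the group mean ± 1 SD. The 6 DMSO libraries lie between 39.2 and 56.7 CPM and the 12 AAI libraries between 201 and 370 CPM.

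A principal component analysis placed treatment first. The first component held 81.6% of the variance, with the DMSO libraries at -96.4 to -87.5, the 3-week fl/fl libraries at 67.7 to 87.9 and the 3-week libraries labelled PTKO at 30 to 58.8. The 6-week libraries lay at 25.6 to 64.3 in fl/fl and at 9.5 to 19.9 in those labelled PTKO. Among the fl/fl 6-week libraries, replicate 2, the shallowest of the 18, lay at 25.6 against 58.8 and 64.3 for the others. The score of adipocyte markers was 5.057 in DMSO replicate 2 and 6.378 in 6-week replicate 2 labelled PTKO, against 3.502 to 3.989 in the other 16 libraries. AAI also changed how the reads were spread over genes. The 10 most abundant genes took 11.6 ± 0.5% of reads in the fl/fl DMSO libraries against 7.8 ± 0.6% at 3 weeks, and 11.3 ± 0.2% against 8.3 ± 1.0% in the libraries labelled PTKO.

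**Figure D2:**
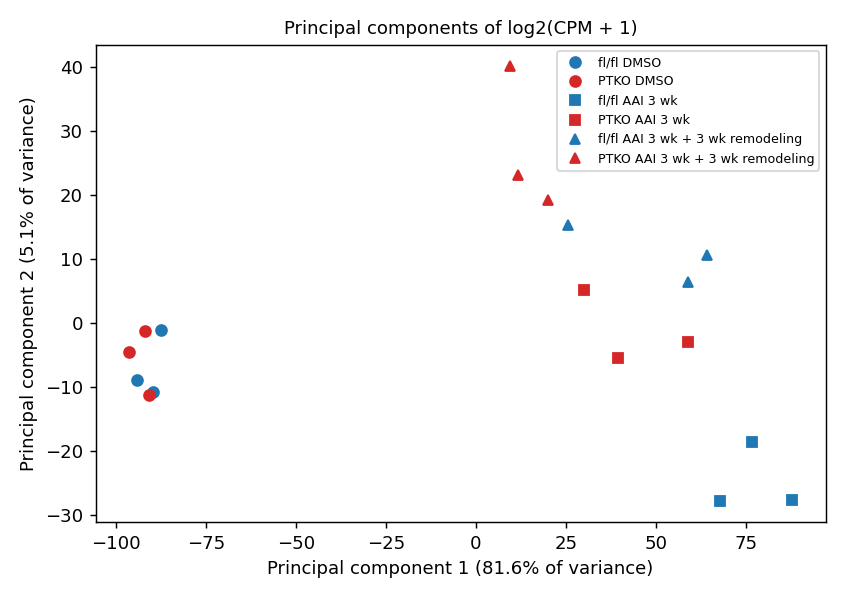
Libraries on the first and second principal components of log2(CPM + 1), which hold 81.6% and 5.1% of the variance; blue is fl/fl, red is labelled PTKO, circles are DMSO, squares 3-week AAI and triangles 6-week AAI. The 6 DMSO libraries lie below -87 on the first component and the 12 AAI libraries above 9.

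The effect of AAI in fl/fl kidneys at the end of treatment was read from the 3-week against the DMSO libraries. Transcripts of injured tubules, macrophages and matrix rose steeply, and transcripts of the proximal tubule and its metabolism fell. Havcr1, which encodes the injury marker KIM-1, rose from 1.71 ± 0.475 to 481 ± 55.8 CPM (7.48, adjusted p = 8.26e-11). Lcn2, the iron-siderophore binding protein NGAL released by injured tubules, rose from 1.84 ± 1.25 to 782 ± 111 CPM (8.18, adjusted p = 4.75e-11). The myeloid genes Gpnmb, Lyz2 (lysozyme) and Mmp12 (macrophage elastase) rose to 662 ± 380, 3530 ± 1000 and 999 ± 384 CPM from 0.607 ± 0.271, 14 ± 2.94 and 4.94 ± 1.36 CPM. The largest falls were in proximal tubule genes. The organic anion transporter Slco1a1 fell from 744 ± 117 to 0.86 ± 0.264 CPM (log2 change -8.65) and the androgen-regulated gene Kap from 29400 ± 2170 to 228 ± 188 CPM (-7.38). The amino acid transporter Slc7a13, the protease inhibitor Pzp and the methyltransferase Inmt fell by 7.25, 6.96 and 6.45 on the log2 scale.

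Of the 14604 genes tested, 11117 changed, 8466 higher and 2651 lower. The median of all tested genes rose by 0.45 in this comparison on CPM and by 0.03 with median-of-ratios scaling, which split the calls into 5353 higher and 4999 lower, and quantile normalization into 4612 and 5682. The medians of the branched-chain amino acid, S1 and S2, S3 and injury lists are therefore also given relative to the median of all genes, and the other medians below hold this shift. Of the 27 genes of branched-chain amino acid catabolism, 25 fell and none rose (median -1.53, -1.98 relative to all genes, camera adjusted p = 3.65e-18). Its call was lost at adjusted p = 0.269 with an estimated correlation, and since the study took this pathway up partly on these samples, the count is not independent evidence of its direction. Bckdha, a subunit of the rate-limiting dehydrogenase complex, fell from 451 ± 29.2 to 153 ± 12.4 CPM, Pcca, of propionyl-CoA carboxylase, from 230 ± 6.26 to 59.7 ± 9.05 CPM, and Abat from 797 ± 42.6 to 135 ± 26.1 CPM. Bckdhb, the partner of Bckdha, fell by 0.82 on the log2 scale (adjusted p = 0.00518). Of the S1 and S2 proximal tubule markers, 18 of 20 fell (median -2.07, -2.52 relative), and all 15 S3 markers fell (median -3.64, -4.09 relative). The phosphate transporter Slc34a1 fell from 8540 ± 625 to 1700 ± 504 CPM, the organic anion transporter Slc22a8 from 843 ± 103 to 57.9 ± 20.7 CPM, and the glucose transporter Slc5a2 from 394 ± 19.4 to 222 ± 45.8 CPM (-0.84, adjusted p = 0.000147). Fatty acid oxidation fell in 23 of 24 genes (median -1.33), nuclear-encoded oxidative phosphorylation in 24 of 26 (-0.76), and gluconeogenesis in 9 of 12 with 2 higher (-1.63), among them the pyruvate carboxylase gene Pcx (1250 ± 62.4 to 213 ± 85.1 CPM). Each of these 5 lists also had an adjusted p = 0.269 with an estimated correlation.

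Every tested member of the tubular injury, extracellular matrix, macrophage and cell cycle lists rose in fl/fl at 3 weeks. The 20 injury genes had a median of 3.96 (3.52 relative), with the adhesion receptor Cd44 rising from 3.31 ± 1.13 to 235 ± 14 CPM (adjusted p = 0.269 with an estimated correlation). For the 28 matrix genes the median was 3.48, and the gelatinase gene Mmp2 rose from 4.14 ± 0.958 to 264 ± 35.7 CPM and Lox, which cross-links collagen, from 3.72 ± 1.12 to 135 ± 16.3 CPM. The 20 macrophage genes had a median of 5.27, with the mannose receptor Mrc1 going from 3.38 ± 0.594 to 268 ± 25.8 CPM. For matrix and macrophages alike the adjusted p = 0.447 with an estimated correlation. The 28 cell cycle genes had a median of 3.01 (adjusted p = 0.449 with an estimated correlation). Chemokines and cytokines rose in 28 of 29 genes with 1 lower (median 3.63, adjusted p = 0.447 with an estimated correlation), and p53 targets in 20 of 24 with 2 lower (median 1.62, adjusted p = 0.345 with an estimated correlation). The cell cycle inhibitor Cdkn1a, a p53 target, rose from 4.39 ± 0.076 to 447 ± 69.8 CPM (6.37, adjusted p = 1.13e-11). Failed-repair tubule markers rose in 14 of 14 (median 3.11, adjusted p = 0.269 with an estimated correlation), 7 members of that list also being in another list, and its complement gene C3 rose from 25 ± 8.42 to 2860 ± 53.8 CPM. Adjusted over the list alone, the counts of all these lists were the same. In total camera called 22 of 33 lists, 14 higher and 8 lower. No camera call in any of the 11 comparisons held with an estimated correlation. The fry test, whose p asks only whether a list's genes move on balance one way and does not compare them with other genes, called 29.

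**Figure D3:**
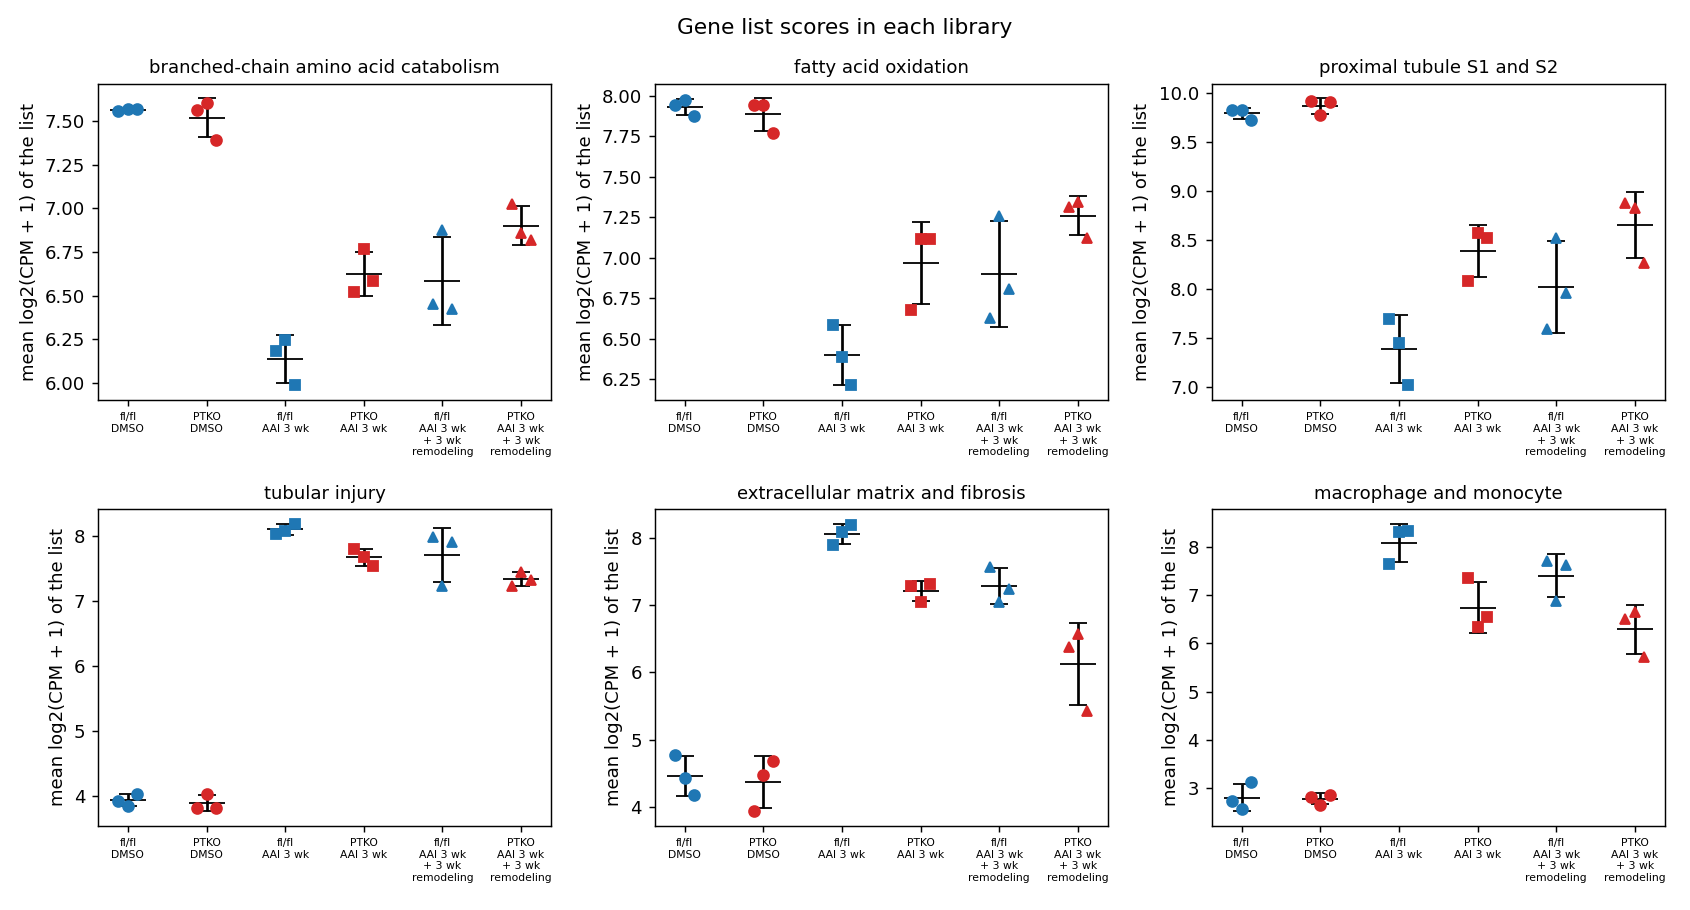
Score of 6 gene lists in each library (mean log2(CPM + 1) of the tested members, vertical axis), with fl/fl in blue and labelled PTKO in red; points are libraries and the horizontal bars with error bars are the group mean ± 1 SD. In fl/fl at 3 weeks the members' median change from DMSO ran from -2.07 for the S1 and S2 proximal tubule list to 5.27 for the macrophage list.

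Whether the AAI state persisted in fl/fl after remodeling was read from the 6-week against the DMSO libraries. The same classes of genes stood out. Havcr1 was at 195 ± 69.8 CPM (6.12 above DMSO), Lcn2 at 458 ± 149 CPM (7.36, adjusted p = 2.59e-10), Gpnmb at 721 ± 457 CPM (8.64, adjusted p = 3.02e-08) and C3 at 1900 ± 552 CPM (6.20, adjusted p = 1.52e-10). The cytochrome P450 genes Cyp2a5 and Cyp4a12a fell from 245 ± 50.2 to 6.05 ± 2.55 CPM (-5.17) and from 249 ± 32.9 to 8.15 ± 7.44 CPM (-5.06), and Slco1a1 was at 34.9 ± 39.1 CPM (-5.03). Slc34a1 was at 1790 ± 414 CPM (-2.28), Slc22a8 at 68.3 ± 33.5 CPM (-3.73), Slc5a2 at 203 ± 44.7 CPM (-0.97, adjusted p = 4.48e-05) and Bckdha at 172 ± 24 CPM (-1.39, adjusted p = 2.77e-08). Bckdhb had a log2 change of -0.42 (adjusted p = 0.123). In all, 10769 genes changed, 8733 higher and 2036 lower, against 4978 and 4746 with median-of-ratios scaling and 4095 and 5314 with quantile normalization. The median of all genes rose by 0.45.

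At 6 weeks in fl/fl, 23 of the 27 branched-chain amino acid genes fell (median -1.01, -1.46 relative to all genes, camera adjusted p = 5.64e-19), a list that is not independent evidence here. Of the S1 and S2 markers 18 of 20 fell (median -1.44), and of the fatty acid oxidation genes 21 of 24 (-1.0). These 3 lists had an adjusted p = 0.223 with an estimated correlation. Oxidative phosphorylation fell in 22 of 26 genes (-0.52, adjusted p = 0.27 with an estimated correlation) and the S3 list in 9 of 15 (-1.29, adjusted p = 0.437 with an estimated correlation, a call that quantile normalization also ended). All 20 injury genes rose (median 3.89, camera adjusted p = 1.62e-07, and adjusted p = 0.249 with an estimated correlation), Cd44 reaching 142 ± 48.7 CPM. All 28 matrix genes rose (2.61, adjusted p = 0.498 with an estimated correlation), with Mmp2 at 165 ± 13.4 CPM and Lox at 93.6 ± 10.2 CPM. All 20 macrophage genes rose (4.46, adjusted p = 0.437 with an estimated correlation), Mrc1 reaching 106 ± 15.3 CPM, and so did all 28 cell cycle genes (1.88, adjusted p = 0.57 with an estimated correlation). The same counts held adjusted over the list alone. Among the class II antigen presentation genes 10 of 10 rose (3.72, adjusted p = 0.57 with an estimated correlation), and Cd74, the invariant chain, went from 263 ± 76.1 to 4290 ± 1150 CPM. Among podocyte markers 13 of 14 rose (1.34, adjusted p = 0.32 with an estimated correlation), with the podocyte cytoskeletal gene Synpo up by 1.46. camera called 21 lists and fry 29.

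The effect of AAI in kidneys labelled PTKO at the end of treatment was read against their own DMSO libraries. Havcr1 rose from 1.18 ± 0.375 to 657 ± 160 CPM (8.22, adjusted p = 5.27e-11), Lcn2 from 2.2 ± 1.17 to 326 ± 35.7 CPM (6.75), C3 from 16.4 ± 3.77 to 1670 ± 229 CPM (6.60) and Lyz2 from 10.8 ± 2.26 to 875 ± 372 CPM (6.15). Serpina10, which encodes the protein Z dependent protease inhibitor, rose from 0.347 ± 0.21 to 148 ± 32.7 CPM (6.77, adjusted p = 2.98e-11). Slco1a1 fell from 674 ± 43.1 to 2.91 ± 3.14 CPM (-7.71), and Pzp, Inmt, Azgp1 and the tyrosine catabolism gene Hpd fell by 6.09, 5.38, 5.35 and 4.91 on the log2 scale. Bckdha fell from 457 ± 21.1 to 195 ± 18.8 CPM (-1.23, adjusted p = 1.05e-07) and the endocytic receptor Lrp2 from 3490 ± 1080 to 707 ± 205 CPM (-2.30). Slc5a2 fell by 0.40 (adjusted p = 0.0317) and Bckdhb by 0.68 on the log2 scale (adjusted p = 0.0174), but both calls were lost without DMSO replicate 1 or 2 labelled PTKO, and that of Slc5a2 also without 3-week replicate 1 or 3 and under quantile normalization. In all, 10386 genes changed, 8354 higher and 2032 lower, against 4807 and 4568 with median-of-ratios scaling and 3947 and 5245 with quantile normalization. The median of all genes rose by 0.42.

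In the 3-week libraries labelled PTKO, 23 of 27 branched-chain amino acid genes (median -1.02, -1.44 relative to all genes, camera adjusted p = 3.05e-18), 20 of 24 fatty acid oxidation genes (-0.92), 23 of 26 oxidative phosphorylation genes (-0.51) and 17 of 20 S1 and S2 markers (-1.19) fell, and none rose. Each of these lists had an adjusted p = 0.254 with an estimated correlation, and the first is not independent evidence. The S3 markers fell in 10 of 15 (-1.43, adjusted p = 0.36 with an estimated correlation). All 20 injury genes rose (3.55, camera adjusted p = 8.4e-08, and adjusted p = 0.254 with an estimated correlation), with the chaperone gene Clu going from 261 ± 35 to 3210 ± 177 CPM. All 28 matrix genes rose (2.65, camera adjusted p = 3e-06), Mmp2 going from 6.67 ± 1.46 to 150 ± 24.3 CPM, and so did all 20 macrophage genes (3.99), with Mrc1 at 123 ± 28 CPM. Both of these lists had an adjusted p = 0.46 with an estimated correlation. The 28 cell cycle genes rose (2.44, adjusted p = 0.5 with an estimated correlation), and 20 of 24 p53 targets (1.49, adjusted p = 0.254 with an estimated correlation), with Cdkn1a going from 9.1 ± 2.96 to 419 ± 29.4 CPM. Adjusted over the list alone, these counts were the same. Cholesterol synthesis gave a call for lower (camera adjusted p = 0.0176, mean -0.03) although its median was 0.09 and 7 genes rose against 5 that fell, and the call was lost with median-of-ratios scaling, with quantile normalization and at adjusted p = 0.46 with an estimated correlation. camera called 22 lists and fry 27.

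At 6 weeks the libraries labelled PTKO were again compared with their DMSO libraries. C3 was at 1890 ± 413 CPM (6.76 above DMSO), Havcr1 at 245 ± 119 CPM (6.69, adjusted p = 1.29e-09), Lcn2 at 264 ± 83 CPM (6.40) and Gpnmb at 160 ± 61.1 CPM (6.19). Slco1a1 was at 13.6 ± 12.9 CPM (-6.33), and the pyrimidine catabolism gene Dpys fell from 24.3 ± 2.36 to 0.278 ± 0.152 CPM (-4.31). Ugt2b38, a glucuronosyltransferase gene that shares sequence with its neighbours in the family, so that its reads are hard to assign, went from 295 ± 255 to 0.104 ± 0.09 CPM (-5.84, adjusted p = 0.00243). Bckdha was at 226 ± 23.8 CPM (-1.02, adjusted p = 1.46e-06). Slc5a2 and Bckdhb had log2 changes of -0.26 (adjusted p = 0.152) and -0.45 (adjusted p = 0.109). In all, 9501 genes changed, 7842 higher and 1659 lower, against 4193 and 4215 with median-of-ratios scaling and 3317 and 4255 with quantile normalization. The median of all genes rose by 0.36.

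In these 6-week libraries 20 of 27 branched-chain amino acid genes (median -0.57, -0.93 relative to all genes, camera adjusted p = 2.84e-15), 18 of 24 fatty acid oxidation genes (-0.68) and 15 of 20 S1 and S2 markers (-0.88) fell. These 3 lists had an adjusted p = 0.245 with an estimated correlation, and the first is not independent evidence. Oxidative phosphorylation fell in 12 of 26 genes with 1 higher (-0.25, adjusted p = 0.426 with an estimated correlation, a call that quantile normalization also ended). Injury genes rose in 19 of 20 (3.14, camera adjusted p = 2.29e-09, and adjusted p = 0.245 with an estimated correlation), macrophage genes in 20 of 20 (3.46, adjusted p = 0.426 with an estimated correlation) and matrix genes in 26 of 28 (1.69, camera adjusted p = 0.000801, and adjusted p = 0.67 with an estimated correlation), with Mmp2 at 84.8 ± 31.6 CPM and Mrc1 at 56.8 ± 14.5 CPM. Adjusted over the list alone, these counts were the same. For the endothelial list the test gave a call for lower (camera adjusted p = 0.0461, mean -0.01) with a median of 0.06 and 3 genes in each direction, among them the VEGF receptor gene Kdr at -1.14. That call was lost with median-of-ratios scaling, quantile normalization and a filter at 5 CPM, without replicate 2 or 3 labelled PTKO of the 6-week or of the DMSO group, and at adjusted p = 0.693 with an estimated correlation. camera called 19 lists and fry 25.

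**Figure D4:**
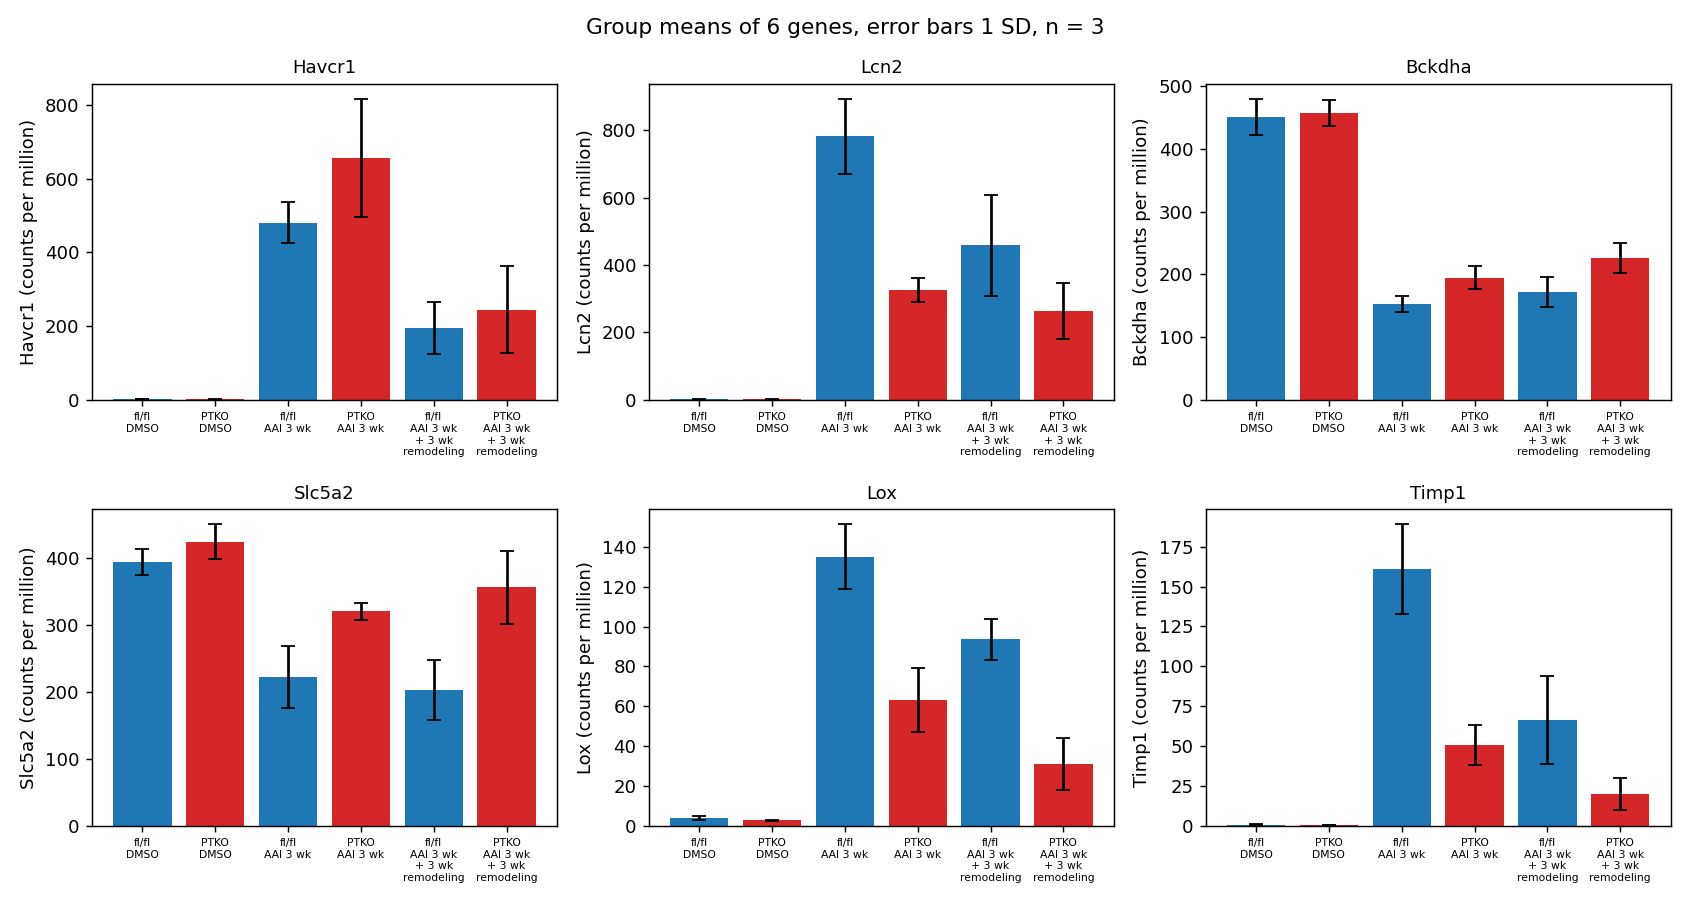
Levels of Havcr1, Lcn2, Bckdha, Slc5a2, Lox and Timp1 (CPM, vertical axes from 0) in the 6 groups, as mean bars with ± 1 SD error bars, with fl/fl in blue and labelled PTKO in red. Lox is at 135 ± 16.3 CPM in fl/fl and 63.1 ± 16 CPM in the libraries labelled PTKO at 3 weeks, and at 93.6 ± 10.2 and 30.9 ± 13 CPM at 6 weeks.

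How far the 3-week changes lasted was counted gene by gene. In fl/fl 7875 of the 8466 genes higher at 3 weeks (93%) were also higher at 6 weeks and 1898 of the 2651 lower genes (71.6%) also lower, against 5063 and 370 for independent calls. In the libraries labelled PTKO these were 7087 of 8354 (84.8%) and 1435 of 2032 (70.6%), against 4486 and 231. With median-of-ratios scaling 4496 of the 5353 genes higher at 3 weeks in fl/fl were also higher at 6 weeks. Of the 4999 lower genes 4276 were also lower. In the libraries labelled PTKO these were 3742 of 4807 and 3671 of 4568. The larger share of higher genes that lasted on CPM was therefore not seen with this scaling. Both times share their DMSO libraries, so chance values are shared as well. In 20 simulations without effects the fold changes at both times correlated at 0.501 across genes in fl/fl and 0.499 in the libraries labelled PTKO, with covariances of 0.0179 and 0.0177, while the data gave correlations of 0.953 and 0.932 and covariances of 1.282 and 0.779. The simulated groups share their controls in the same way, and 0 genes were called at both times in them. With covariances this far apart, shared control noise is argued against as the source of most of the excess. Genes are not independent replicates, and the simulated noise was drawn for each gene on its own. The 3 control libraries are too few to split between the times, so a small part from the shared controls stays possible.

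Change over the remodeling time in fl/fl was read from the 6-week against the 3-week libraries. Genes of the S3 proximal tubule and thick limb rose and cell cycle genes fell. Kap rose from 228 ± 188 to 6840 ± 5470 CPM (4.99, adjusted p = 0.0024), the medium-chain acyl-CoA ligase gene Acsm3 from 21.4 ± 16.2 to 559 ± 409 CPM, and Slc7a13 from 10.7 ± 11.1 to 256 ± 197 CPM. Slc5a8, a monocarboxylate transporter of S3, rose from 20.4 ± 15.2 to 166 ± 96.5 CPM (3.04, adjusted p = 0.000746), and Egf, made in the thick limb and distal tubule, from 93.8 ± 77.6 to 531 ± 350 CPM (2.58). The matrix proteoglycan gene Vcan fell from 25 ± 1.39 to 7.25 ± 1.1 CPM (-1.66, adjusted p = 2e-04) and Cdkn1a by 1.28 on the log2 scale (adjusted p = 0.00244). Havcr1 fell from 481 ± 55.8 to 195 ± 69.8 CPM (-1.36, adjusted p = 0.0164), a call lost without 3-week replicate 3 or 6-week replicate 2. Lcn2 had a log2 change of -0.82 (adjusted p = 0.108). Of the 28 cell cycle genes 15 fell, or 28 adjusted over the list alone (median -1.04, camera adjusted p = 9.09e-13), of the 15 S3 markers 14 rose by either adjustment (2.39), and of the 10 thick limb markers 7 rose, or 10 adjusted over the list alone (1.22). Branched-chain amino acid genes rose in 14 of 27, or 18 adjusted over the list alone (0.43, camera adjusted p = 1.48e-08), a count that is not independent evidence, and matrix genes fell in 6 of 28, or 13 adjusted over the list alone (-0.82). All 5 lists had an adjusted p = 0.43 with an estimated correlation. Of the S1 and S2 markers 3 of 20 rose, or 4 with 1 lower adjusted over the list alone (0.46, camera adjusted p = 0.00575, and adjusted p = 0.474 with an estimated correlation), a call lost without 3-week replicate 3 or 6-week replicate 2. The S3 score was 8.813 in 6-week replicate 2 against 7.522 and 7.186 in the other 2 libraries. In 3-week replicates 1, 2 and 3 the S3 score was 4.643, 5.811 and 5.094, and the thick limb score 5.385, 6.444 and 5.674. Both lists ranked these libraries alike, so their rises may not be separate changes. In 6-week replicates 1, 2 and 3 the thick limb score was 7.621, 7.412 and 6.753, in another order than S3. In all, 1932 genes changed, 1046 higher and 886 lower, against 840 and 1076 with median-of-ratios scaling, 1152 and 1263 with quantile normalization and 1202 and 1284 with DESeq2. The count was 1213 without 3-week replicate 2, 642 without 3-week replicate 3 and 643 without 6-week replicate 2, and 562 in a fit on the compared groups alone, in which Egf was not past the threshold.

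The same comparison in the libraries labelled PTKO gave falls in cell cycle and matrix genes. Thbs1, an activator of TGF-beta, fell from 795 ± 50.1 to 299 ± 79.8 CPM (-1.44), and Vcan fell by 1.60. The contactin gene Cntn2 fell from 27.1 ± 7.42 to 2.16 ± 1.54 CPM (-3.25), and Serpina6, which encodes corticosteroid-binding globulin, from 58.7 ± 19.3 to 10.1 ± 4.27 CPM (-2.44, adjusted p = 0.000881). Havcr1 fell from 657 ± 160 to 245 ± 119 CPM (-1.53, adjusted p = 0.0105), and Inmt rose from 24.5 ± 10.7 to 135 ± 78.8 CPM (2.36). Of the cell cycle genes 24 of 28 fell, or 26 adjusted over the list alone (median -1.36, camera adjusted p = 3.35e-14), and of the matrix genes 16 of 28, or 23 adjusted over the list alone (-1.06). Branched-chain amino acid genes rose in 7 of 27, or 14 adjusted over the list alone (0.30, not independent evidence), oxidative phosphorylation genes in 7 of 26, or 20 (0.27), and thick limb markers in 6 of 10, or 8 (1.0). These 5 lists had an adjusted p = 0.343 with an estimated correlation. In 6-week replicate 3 the score of matrix genes was 5.425 against 6.377 and 6.567, of cell cycle genes 2.115 against 3.066 and 3.233, and of thick limb markers 8.398 against 7.565 and 7.143. No S1 and S2 or S3 marker passed over all genes with limma (medians 0.25 and 0.75, adjusted p = 0.551 with an estimated correlation for both). At an unadjusted p under 0.05 these were 1 and 0, with edgeR 0 and 0, and with DESeq2 1 and 0. In all, 1633 genes changed, 426 higher and 1207 lower, against 535 and 854 with median-of-ratios scaling. The count was 536 without 3-week replicate 1, 666 without 3-week replicate 3 and 785 without 6-week replicate 1, and 367 in a fit on the compared groups alone, in which Havcr1 was not past the threshold.

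The genotypes were first compared under DMSO, which asks what the PTKO label carries before injury. Few genes differed. Angptl7, a secreted angiopoietin-like protein (chromosome 4, 148495183 to 148500460), was at 420 ± 126 CPM in the libraries labelled PTKO against 34 ± 5.52 CPM in fl/fl (3.55 ± 0.40 SE, adjusted p = 0.000317). Fam213b, a prostamide synthase gene on chromosome 4 (154895504 to 154899135), was at 47.6 ± 18.1 against 6.63 ± 0.829 CPM (2.62, adjusted p = 2.1e-06), and the GDNF receptor gene Gfra1 at 39.5 ± 10.9 against 6.03 ± 0.777 CPM (2.50, adjusted p = 0.00299). Hprt, the purine salvage enzyme gene on chromosome X (52988137 to 53021659), was lower at 23.2 ± 6.54 against 71.2 ± 2.91 CPM (-1.62, adjusted p = 0.000179), and Ogdhl, which is related to a subunit of the oxoglutarate dehydrogenase complex, at 0.67 ± 0.246 against 5.19 ± 1.13 CPM (-1.88). Eno1b, a copy of the enolase gene Eno1 was at 6.03 ± 2.21 against 0.0339 ± 0.0587 CPM (adjusted p = 1.35e-06), but reads of such copies are hard to assign. Havcr1, Lcn2, Slc5a2 and Bckdhb had log2 differences of -0.31, 0.18, 0.11 and -0.20, each with an adjusted p = 1. No gene of the branched-chain amino acid, S1 and S2, injury or matrix lists passed over all genes (medians -0.04, 0.10, -0.08 and -0.16) or adjusted over the list alone with limma, nor by edgeR or DESeq2, and 0, 1, 1 and 2 of them had an unadjusted p under 0.05. Of the 24 fatty acid oxidation genes 1 was higher, Eci1, at 96.3 ± 3.06 against 62.6 ± 1.52 CPM (0.61, adjusted p = 0.0192), a list in which edgeR called 0 and DESeq2 1. camera called 7 lists, among them neutrophil markers higher (median 0.49, camera adjusted p = 0.000923) and B and plasma cell markers higher (0.51), but none of their members passed with limma (2 and 1 at an unadjusted p under 0.05, 0 with edgeR, 1 and 0 with DESeq2), the adjusted p ran from 0.873 to 0.997 with an estimated correlation, and fry called 0 lists (1 at an unadjusted p under 0.05). Joining chain Igj, of plasma cells, was at 231 ± 24.6 against 105 ± 51.2 CPM (adjusted p = 0.457).

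In all, 42 genes differed under DMSO, 28 higher and 14 lower in the libraries labelled PTKO, and 954 had an unadjusted p under 0.05. Quantile normalization gave 24 higher and 7 lower. The count was 26 without fl/fl DMSO replicate 1 and 26 without replicate 2, 18 in a fit on the compared groups alone and 113 with DESeq2, and of the 10 most changed genes named by the rule, the 6 given above stayed past the threshold whichever library was left out, though Hprt did not in the fit on the compared groups alone.

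At 3 weeks of AAI the genotypes were compared to ask whether injury differed with the label. Most S1, S2 and S3 proximal tubule markers were higher in the libraries labelled PTKO than in fl/fl, and most macrophage genes lower. The share of reads of Rn45s, the precursor of ribosomal RNA, was 0.465 ± 0.067% in the libraries labelled PTKO and 0.602 ± 0.068% in fl/fl, and under DMSO 0.451 ± 0.012% and 0.483 ± 0.037%. Serpina6 was at 58.7 ± 19.3 against 2.74 ± 0.0869 CPM (3.94 ± 0.32 SE, adjusted p = 4.66e-06), the fatty acid hydroxylase gene Cyp4a12a at 75.5 ± 14.7 against 6.64 ± 1.8 CPM (3.33, adjusted p = 0.00256) and the aldo-keto reductase gene Akr1c14 at 86.2 ± 51.8 against 8.1 ± 5.93 CPM (3.29). Cyp4a12a was also higher under DMSO, at 685 ± 98.4 against 249 ± 32.9 CPM, though not past the threshold there (1.45, adjusted p = 0.518). Arg1, arginase of alternatively activated macrophages, was lower at 2.74 ± 3.66 against 36.4 ± 10.3 CPM (-3.73, adjusted p = 0.0017), Gpnmb at 92.2 ± 113 against 662 ± 380 CPM (-3.32), Mmp12 at 158 ± 165 against 999 ± 384 CPM (-3.09) and Hprt at 11.2 ± 1.75 against 103 ± 14.4 CPM (-3.10, adjusted p = 8.82e-08). Lcn2 was lower at 326 ± 35.7 against 782 ± 111 CPM (-1.26, adjusted p = 0.0217) and Slc5a2 higher at 320 ± 13 against 222 ± 45.8 CPM (0.55, adjusted p = 0.0321). Havcr1 had a difference of 0.43 (adjusted p = 0.412) and Bckdhb of -0.06 (adjusted p = 0.897).

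Among the lists, 15 of 27 branched-chain amino acid genes were higher in the 3-week libraries labelled PTKO, or 20 adjusted over the list alone, and none lower (median 0.53, camera adjusted p = 6.65e-11), a count that is not independent evidence. Abat, which degrades GABA, was at 287 ± 34.7 against 135 ± 26.1 CPM (1.09, adjusted p = 0.0029) and Aldh6a1, of valine breakdown, at 471 ± 85 against 233 ± 65.3 CPM (1.03, adjusted p = 0.00684). Of the S1 and S2 markers 13 of 20 were higher, or 17 adjusted over the list alone (0.90, camera adjusted p = 6.65e-11), and of the S3 markers 12 of 15, or 14 (1.86), with the amino acid transporter Slc6a18 at 391 ± 58.6 against 121 ± 31 CPM and Slc5a8 at 133 ± 45.2 against 20.4 ± 15.2 CPM. Fatty acid oxidation was higher in 11 of 24 genes, or 16 (0.46), and gluconeogenesis in 7 of 12, or 8 (0.79), with the malate dehydrogenase gene Mdh1 at 852 ± 93.4 against 515 ± 71.9 CPM. Macrophage genes were lower in 15 of 20, or 19 adjusted over the list alone (-1.24, camera adjusted p = 6.65e-11), with Mrc1 at 123 ± 28 against 268 ± 25.8 CPM, the microglial and macrophage receptor gene Trem2 at 17.2 ± 7.83 against 68.8 ± 27.7 CPM and Lyz2 at 875 ± 372 against 3530 ± 1000 CPM. These 6 lists had an adjusted p = 0.329 with an estimated correlation. Oxidative phosphorylation was higher in 8 of 26 genes, or 20 adjusted over the list alone (0.28, camera adjusted p = 2.74e-10, and adjusted p = 0.366 with an estimated correlation), or 16 with DESeq2. Matrix genes were lower in 10 of 28, or 16 adjusted over the list alone (-0.85, camera adjusted p = 1.52e-07, and adjusted p = 0.448 with an estimated correlation), among them Lox and the fibronectin gene Fn1 at 650 ± 164 against 1750 ± 217 CPM (-1.45). Chemokines were lower in 9 of 29, or 12 (-0.57), with Ccl6 at 114 ± 51.9 against 478 ± 114 CPM, and injury genes in 5 of 20, or 6 (-0.40, camera adjusted p = 0.0122), with Anxa1 at 77.1 ± 17.8 against 187 ± 45.2 CPM and the metalloproteinase inhibitor gene Timp1 at 50.8 ± 12.6 against 161 ± 28 CPM. Both of these lists had an adjusted p = 0.538 with an estimated correlation.

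In all, 2077 genes differed at 3 weeks, 908 higher and 1169 lower in the libraries labelled PTKO, against 993 and 960 with median-of-ratios scaling, 1144 and 1195 with quantile normalization, 1128 and 836 with edgeR and 1406 and 1299 with DESeq2. Without fl/fl replicate 2 it was 520 and 485, and without replicate 3 labelled PTKO 407 and 406, so that which share is larger is not settled. The count was 1005 without fl/fl replicate 2, 424 without fl/fl replicate 3, 360 without replicate 2 labelled PTKO and 813 without replicate 3 labelled PTKO, and it was 3228 when 3 libraries of other groups that stood apart were left out of the shared fit. Of the 63 genes named by the rule that passed, 25 passed whichever library was left out, and of those given above Gpnmb, Mmp12, Lcn2, Slc5a2, Lox, Fn1 and Timp1 were not past the threshold without replicate 2 labelled PTKO. Gpnmb, Lcn2, Slc5a2, Fn1 and Timp1 were not past it without fl/fl replicate 3 either, nor Lcn2 and Slc5a2 without fl/fl replicate 2 or replicate 3 labelled PTKO, nor Lcn2 with a pseudocount of 0.1.

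At 6 weeks the genotypes were compared to ask whether the state after remodeling differed with the label. Matrix and macrophage genes were among those lower in the libraries labelled PTKO, and most oxidative phosphorylation genes were higher. The precursor of ribosomal RNA, Rn45s, took 0.46 ± 0.059% of reads in these libraries and 0.638 ± 0.108% in fl/fl. Angptl7 was again higher, at 124 ± 57.3 against 9.15 ± 3.05 CPM (3.54, adjusted p = 0.000141), and the interferon-induced chemokine gene Cxcl11 was at 10.5 ± 4.13 against 1.02 ± 0.329 CPM (2.45). Ugt1a2, which shares exons with the rest of its locus, was at 100 ± 127 against 3.57 ± 3.07 CPM (3.83, adjusted p = 0.00382). Hprt was lower at 13.4 ± 2.08 against 96.9 ± 3.21 CPM (-2.77, adjusted p = 2.36e-07), the kinase gene Camk2b at 0.778 ± 0.0902 against 12.3 ± 2.58 CPM (-2.88) and the lysozyme gene Lyz1 at 11.7 ± 6.44 against 65.7 ± 8.05 CPM (-2.57). Slc5a2 was higher at 356 ± 54.7 against 203 ± 44.7 CPM (0.82, adjusted p = 0.00533). Havcr1, Lcn2 and Bckdhb had differences of 0.26 (adjusted p = 0.634), -0.78 (adjusted p = 0.117) and -0.23 (adjusted p = 0.548).

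Matrix genes were lower in 20 of 28 at 6 weeks, or 26 adjusted over the list alone (median -1.10, camera adjusted p = 7.04e-10, and adjusted p = 0.395 with an estimated correlation). Lox was at 30.9 ± 13 against 93.6 ± 10.2 CPM (-1.63, adjusted p = 0.000922), tenascin Tnc at 49.4 ± 24.6 against 128 ± 21.6 CPM (-1.48) and Mmp14 at 89.7 ± 9.19 against 202 ± 44.1 CPM (-1.15). Macrophage genes were lower in 12 of 20, or 18 adjusted over the list alone (-1.05, camera adjusted p = 1.37e-06), and fibroblast and pericyte genes in 4 of 14, or 11 (-0.69), with Tagln, a smooth muscle and myofibroblast gene, at 65 ± 20.6 against 142 ± 34.9 CPM. Both of these lists had an adjusted p = 0.448 with an estimated correlation, and the fibroblast call was also lost without replicate 3 labelled PTKO. With edgeR the lower genes were 13 of 28 for matrix, 8 of 20 for macrophages and 2 of 14 for fibroblasts and pericytes. That library stood apart, with a matrix score of 5.425 against 6.377 and 6.567 in replicates 1 and 2, a macrophage score of 5.718 against 6.503 and 6.638, and a thick limb score of 8.398 against 7.565 and 7.143. Oxidative phosphorylation genes were higher in 18 of 26, or all 26 adjusted over the list alone (0.34, camera adjusted p = 5e-20, and adjusted p = 0.236 with an estimated correlation), with Sdhb, of succinate dehydrogenase, at 332 ± 25.6 against 227 ± 39.2 CPM. Branched-chain amino acid genes were higher in 9 of 27, or 14 adjusted over the list alone (0.32, camera adjusted p = 3.8e-11, and adjusted p = 0.277 with an estimated correlation), a count that is not independent evidence, with Mut, methylmalonyl-CoA mutase, at 220 ± 14.7 against 132 ± 35.5 CPM. Fatty acid oxidation genes were higher in 6 of 24, or 9 (0.31, adjusted p = 0.284 with an estimated correlation), with Eci1, which also differed under DMSO, at 83.9 ± 6.38 against 44.1 ± 5.63 CPM (0.92, adjusted p = 0.000205), and S1 and S2 markers in 7 of 20, or 9 (0.56, adjusted p = 0.268 with an estimated correlation), with the amino acid transporter Slc7a7 at 345 ± 7.27 against 173 ± 28.1 CPM and Slc22a8 at 237 ± 29.2 against 68.3 ± 33.5 CPM. The injury list was not called (median -0.31, camera adjusted p = 0.148), with 5 of its 20 genes lower, among them Timp1 at 19.8 ± 9.99 against 66.2 ± 27.4 CPM (-1.75).

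In all, 2198 genes differed at 6 weeks, 477 higher and 1721 lower in the libraries labelled PTKO, against 811 and 907 with median-of-ratios scaling, 871 and 852 with quantile normalization and 823 and 677 with edgeR. The count was 441 without fl/fl replicate 1, 3765 without fl/fl replicate 2, 841 without fl/fl replicate 3 and 1107 without replicate 1 labelled PTKO, 4545 without the 3 libraries that stood apart, and 163 in a fit on the compared groups alone, in which Tnc, Tagln, Timp1, Slc5a2, Slc22a8, Sdhb, Mut and Ugt1a2 were not past the threshold. Mut was also not past it without fl/fl replicate 1 or 3.

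Whether the AAI response itself differed with the label was tested as the genotype by AAI interaction. At 3 weeks 41 genes passed, 24 with a higher and 17 with a lower response in the libraries labelled PTKO, against 20 and 27 with median-of-ratios scaling, and 2711 had an unadjusted p under 0.05. Serpina6 had an interaction of 4.38 (adjusted p = 0.000554), the fructose transporter Slc2a5 of 1.82 (adjusted p = 0.00642), and Fam213b, which differed under DMSO, of -1.88 (adjusted p = 0.0109). These 3 were the ones of the 10 genes named by the rule that passed whichever library was left out. For Havcr1 the interaction was 0.74 (adjusted p = 0.418), for Lcn2 -1.44 (adjusted p = 0.123), for Slc5a2 0.44 (adjusted p = 0.302) and for Bckdhb 0.14. Branched-chain amino acid genes had a median interaction of 0.57 (camera adjusted p = 4.36e-10), 0 passing over all genes with limma and 13 adjusted over the list alone, and macrophage genes a median of -1.30, 0 passing and 13 lower adjusted over the list alone. At an unadjusted p under 0.05 they were 17 and 14, with edgeR 0 and 0, and with DESeq2 6 and 8. Both lists had an adjusted p = 0.312 with an estimated correlation. The list scores gave an interaction of 0.53 for branched-chain amino acids (exact permutation p = 0.04, adjusted 0.22 over 66 relations) and of -1.32 for macrophages (exact permutation p = 0.08, adjusted 0.27). Without 1 library the 3-week count was 6, 6 and 11 for fl/fl DMSO replicates 1, 2 and 3, 9, 26 and 6 for DMSO replicates 1, 2 and 3 labelled PTKO, 332 and 7 for fl/fl 3-week replicates 1 and 3, and 427, 7 and 12 for 3-week replicates 1, 2 and 3 labelled PTKO. It was 18 with edgeR, 588 with DESeq2, 581 in a fit on the compared groups and 392 without the 3 libraries that stood apart.

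At 6 weeks 10 genes passed the interaction test, 4 with a higher and 6 with a lower response, against 8 and 5 with median-of-ratios scaling, and 2132 had an unadjusted p under 0.05. Wnt5b, a secreted signalling protein, had an interaction of 1.51 and the matrix protease gene Mmp7 of -2.37 (adjusted p = 0.0161 for both). Matrix genes had a median interaction of -1.13, 0 passing over all genes with limma and 17 lower adjusted over the list alone (adjusted p = 0.308 with an estimated correlation), and branched-chain amino acid genes one of 0.38 with 0 passing by either adjustment (adjusted p = 0.25 with an estimated correlation). In these lists 19 and 13 genes had an unadjusted p under 0.05, edgeR called 0 and 0, and DESeq2 3 and 0. The list scores gave interactions of 0.36 for branched-chain amino acids (exact permutation p = 0.14), -1.09 for macrophages (exact permutation p = 0.09) and -1.07 for matrix genes (exact permutation p = 0.11). Without 1 library the count was 0 and 4 for fl/fl DMSO replicates 1 and 2, 5 and 5 for DMSO replicates 1 and 2 labelled PTKO, 0 and 250 for fl/fl 6-week replicates 1 and 2, and 6 for 6-week replicate 1 labelled PTKO. It was 1 with edgeR, 89 with DESeq2 and 279 without the 3 libraries that stood apart, and none of the 8 genes named by the rule passed whichever library was left out.

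The size of the response was compared over the 500 genes with the largest average response, so the result holds for strong responders only. At 3 weeks, when 441 of them rose and 59 fell, the mean response was 4.34 in fl/fl and 3.54 in the libraries labelled PTKO, a difference of -0.80 (exact permutation p = 0.065 over 400 assignments), and 446 of the 500 genes responded less in the libraries labelled PTKO. At 6 weeks the means were 3.65 and 2.90, a difference of -0.74 (exact permutation p = 0.105), with 451 of 500 genes responding less. Neither difference passed an exact test at 0.05. Gene lists did not all follow these genes. The score of p53 targets was 6.15 in both genotypes at 3 weeks and 5.64 in both at 6 weeks. The macrophage score was 8.08 in fl/fl and 6.74 in the libraries labelled PTKO at 3 weeks, and 7.40 and 6.29 at 6 weeks.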

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

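The tests of chromosome segments, of the matrix list with the proximal tubule score, of thinned reads, of male-biased genes against random tubule lists and of the female-biased list were tests chosen only after the results or the data were seen. What drew attention to each gene given with an interaction in this part was a response to AAI that differed between the genotypes by the interaction test. No group has 4 or more libraries, so single libraries far from their group were not tested.

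The first pattern is the set of 42 genes that differed between the genotypes under DMSO, before any injury. An effect of the single DMSO library replicate 3 labelled PTKO is argued against for 22 of the 42 genes. These were also called in the same direction at both AAI times, in libraries that do not include it. For the rest of the 42 genes such an effect stays possible. Without that library 66.7% of the calls stayed (28 of 42), exactly the share set beforehand as the bound, and leaving out fl/fl DMSO replicate 1 or 2 left fewer (26 each). The called genes sat close to each other more often than random tested genes, with 11 pairs within 5 Mb against a 95th percentile of 8 in 10000 random sets (permutation p = 0.009), which is consistent with chromosome segments of another strain background that travel with the genotype. This stays a hypothesis found on the same data, as no sequence variants were analysed here. An effect of the knockout itself, the biological explanation the design gives, was not excluded. None of the 38 called genes with a known position lies on the chromosome of Klf6 (the other 4 have none). That cannot count for or against linked segments on other chromosomes.

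The second pattern is the smaller AAI response of the 500 strongest responders in the libraries labelled PTKO, -0.80 at 3 weeks and -0.74 at 6 weeks. The authors' CPM scaling as the cause is argued against, since median-of-ratios scaling kept 0.88 or more of the difference, and so is a difference in library depth, since thinning to the shallowest library kept a ratio of 1 or more. The share of proximal tubule transcripts in the cortex was examined for gene lists only, not for the 500 genes. A different share may account for the genotype difference of the branched-chain amino acid list. With the S1 and S2 score as a covariate that difference was 0.2 of its size at both times (0.53 to 0.10 and 0.32 to 0.06). The ratios at 3 and 6 weeks were -0.02 and 0.12 for fatty acid oxidation and 0.18 and 0.36 for gluconeogenesis. They were 0.32 and 0.67 for oxidative phosphorylation and 0.6 and 0.79 for macrophage genes. For the matrix list the difference with the covariate was 1.03 times its size or more (-0.85 to -0.95 and -1.10 to -1.14). This cannot decide, since the slope of the covariate comes from the spread within groups and can lean on 1 library. In fl/fl at 3 and at 6 weeks the library with the lowest S1 and S2 score had the highest matrix score. In 6-week replicate 3 labelled PTKO both scores were the lowest of its group (8.271 and 5.425), and a fit without it was not run. Whether more tubule survived or its genes were more active, and whether Klf6 or a linked segment lies behind it, stays open, and the exact permutation p of 0.065 and 0.105 do not pass 0.05.

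The third pattern is the loss of male-biased proximal tubule transcripts after AAI, of which 12 of 13 fell in fl/fl and 11 of 13 in the libraries labelled PTKO at 3 weeks (medians -5.05 and -3.07). A lower share of proximal tubule transcripts alone stays open. It was tested on the 8 members that were not among the largest falls named by the rule. Of these, Slc22a30, Cyp7b1 and Acsm3 are S3 markers, so they were not unseen and also sit in the pool of markers. The 8 fell more than 81.73% of random lists drawn from all 35 S1, S2 and S3 markers in fl/fl (median -3.33 against -2.52). In the libraries labelled PTKO they fell more than 97.97% (-2.45 against -1.29), where 95% in both was the bound. Only without the 7 sex-biased markers was that bound passed in both (97.57% and 100%). Less androgen signalling as the sole cause is argued against in fl/fl only if the members of the female-biased list are female-biased in kidney. That was assumed and not tested here. Such a loss would then raise the list, but 0 of its 7 members were higher in fl/fl by limma, by edgeR, by DESeq2 and at an unadjusted p under 0.05. By each of these 6 were lower, among them Cyp2a4 (-6.07 by limma), Slc22a7 (-5.38) and Slc22a19 (-3.64). In the libraries labelled PTKO less androgen signalling stays open, since at 3 weeks 2 members were lower and 1 higher (median 0), too few to decide. The lower members were Cyp2a4 (-4.15) and Slc22a7 (-2.73), and the higher was Slc7a12 (3.22, adjusted p = 0.000142). At 6 weeks 2 were higher, Slc7a12 and Prlr (2.47, adjusted p = 0.00276), and 1 lower, Cyp2a4 (-1.94), with a list median of 0.34. A loss of androgen response together with a loss of S3 cells, in which both lists are expressed, could not be separated here, and the sex of the mice was not used in the tests. The score of the Y-linked control list ran from 4.836 to 5.451 over the 18 libraries, so none lacked Y-linked transcripts. These values argue against a difference in sex between the groups.

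At 3 weeks Serpina6 had an interaction of 4.38 (adjusted p = 0.000554), Slc2a5 of 1.82 (0.00642), Reep6 of 1.36 (0.00558) and Wnt5b of 1.22 (0.0338). Reep6 was already lower under DMSO in the libraries labelled PTKO (-0.64, adjusted p = 0.0343). Slc5a8, of S3, had an interaction of 3.08 (adjusted p = 0.045), the carboxylesterase gene Ces1d of 1.98 (0.0482), the NRF2 target Nqo1 of 1.46 (0.042) and Serpina1b, whose reads are shared with its close copies, of 2.42 (0.045). Lower responses in the libraries labelled PTKO were those of the macrophage receptor genes Cd300lf (-1.93, adjusted p = 0.045) and Cd163 (-1.88, 0.045), Fam213b (-1.88, 0.0109), Mmp7 (-1.65, 0.0482), Gda (-1.53, 0.045) and Hprt (-1.48, 0.0277). At 6 weeks Serpina6 had an interaction of 2.79 (adjusted p = 0.0345), Gsta3 of 1.52 (0.049), Wnt5b of 1.51 (0.0161) and Reep6 of 1.10 (0.0345). Lower 6-week responses were those of Mmp7 (-2.37, adjusted p = 0.0161), Piezo2 (-1.75, 0.049), Pdpn (-1.59, 0.0399) and Synj2 (-1.34, 0.049). The 3-week calls of Slc5a8, Ces1d, Serpina1b, Cd300lf, Cd163, Mmp7 and Gda were lost with edgeR, without a filter, and without any 1 of fl/fl DMSO replicates 1 to 3, DMSO replicates 1 and 3 labelled PTKO, fl/fl 3-week replicate 3 and 3-week replicate 2 labelled PTKO. All 8 of the 6-week calls were lost without fl/fl DMSO replicate 1 or fl/fl 6-week replicate 1, and all but that of Wnt5b with edgeR.

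Other splits of the same libraries were counted for each comparison. In the comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each the real split was the only 1 to call as many genes. The real count and the highest of the other splits were 11117 and 0 for fl/fl AAI at 3 weeks, 10769 and 0 at 6 weeks, 10386 and 1 in the libraries labelled PTKO at 3 weeks, and 9501 and 19 at 6 weeks. Between genotypes they were 42 and 2 under DMSO, 2077 and 4 at 3 weeks, and 2198 and 1235 at 6 weeks. Between the times they were 1932 and 1 in fl/fl and 1633 and 0 in the libraries labelled PTKO. For the interaction at 3 weeks 4 of 100 splits called as many genes as the real 41, a share under 0.05, but the highest of the others called 300, several times the real count. A split for the interaction can keep the real genotypes among the AAI or among the DMSO libraries, and the source of that high count was not tested. For the interaction at 6 weeks 10 of 100 splits called as many as the real 10, so chance is not excluded there. The highest called 286, and the source of that count was not tested either.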

How the results depend on the processing

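The tests with fry, with thinned reads and without the 3 libraries that stood apart (fl/fl 6-week replicate 2, 6-week replicate 3 labelled PTKO and DMSO replicate 3 labelled PTKO) were chosen only after the data were seen. The AAI against DMSO counts stayed within 1.5 times their reported values in every alternative but the fold minimum, and the rise of Klf6 kept its direction and its call in each of the 4 comparisons of AAI with DMSO. In the other comparisons Klf6 was called under no alternative, and its direction varied. Of the values for single named genes 10459 kept call and direction, 809 lost the call, 43 gained one and 1 reversed. That was Cldn5 at 6 weeks in the libraries labelled PTKO, at 0.51 as reported and -0.19 under quantile normalization. Of the values for single lists 2576 kept their call, 446 lost it and 12 gained one. Where a main count changed, the cause was not tested, except that a higher fold minimum admits fewer genes. Depth limits genes near 1 CPM most in fl/fl 6-week replicate 2, where 1 read is 0.0853 CPM.

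The interaction counts of 41 (3 weeks) and 10 (6 weeks) moved most. The 6-week count was 1 with a pseudocount of 0.1. The 3-week count was 7 without a filter, 12 without a variance trend and 74 with the replicate block. With a filter at 5 CPM the counts were 64 and 5, with quantile normalization 88 and 18, with edgeR 18 and 1, with DESeq2 588 and 89, and without the 3 libraries that stood apart 392 and 279. In a fit on the compared groups alone the 3-week interaction had 581 calls, the DMSO genotype comparison 18 (42 as reported), the 6-week genotype comparison 163 (2198), 6 against 3 weeks 562 in fl/fl (1932) and 367 in the libraries labelled PTKO (1633). DESeq2 called 113 under DMSO. Without the 3 libraries the genotype counts were 3228 at 3 weeks and 4545 at 6 weeks, and fl/fl 6 against 3 weeks 1253. With a log2 fold change of at least 1 required, the AAI counts were 4904 and 4172 in fl/fl and 3888 and 2968 in the libraries labelled PTKO, the genotype counts 24, 470 and 489, and the counts between times 403 and 329.

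The genes called at 3 weeks and again at 6 weeks (fl/fl higher, fl/fl lower, labelled PTKO higher, labelled PTKO lower) were 4496, 4276, 3742 and 3671 with median-of-ratios scaling and 3647, 4747, 2861 and 3763 with quantile normalization. They were 4464, 4254, 4009 and 3411 with edgeR, and 4535, 4249, 3953 and 3718 with DESeq2. With an estimated correlation camera called 0 lists in each of the 11 comparisons (from 1 to 6 at an unadjusted p under 0.05). fry called 0 lists under DMSO (1 at an unadjusted p under 0.05, and camera 7), 13 in each genotype comparison after AAI, 11 in fl/fl and 5 in the libraries labelled PTKO between the times, and 1 and 3 for the interactions.

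Leaving out each library in turn gave ranges. Counts of changed genes ran from 10520 to 10804 and from 9868 to 10798 for AAI in fl/fl, from 9395 to 10066 and from 8496 to 8975 for AAI in the libraries labelled PTKO, from 26 to 53, 360 to 2517 and 441 to 3765 between genotypes, from 642 to 1917 and 536 to 1623 between times, and from 6 to 427 and 0 to 250 for the interactions. Lists called ran from 22 to 23, 20 to 22, 21 to 23 and 18 to 21 for AAI, from 5 to 8, 15 to 20 and 15 to 25 between genotypes, from 18 to 25 and 16 to 24 between times, and from 18 to 23 and 17 to 26 for the interactions. Genes called at both times ran from 7319 to 7882, 1658 to 1991, 6339 to 6935 and 1264 to 1393. The difference in response size ran from -0.969 to -0.655 and from -0.994 to -0.587. For Klf6 the AAI effects ran from 2.68 to 2.82, 2.50 to 2.75, 2.43 to 2.67 and 2.36 to 2.71, the genotype differences from 0.044 to 0.288, -0.137 to 0.079 and -0.05 to 0.298, those between times from -0.255 to -0.006 and -0.169 to 0.179, and the interactions from -0.329 to -0.085 and -0.24 to 0.112.

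The replicate numbers share only a number between groups. Deviations from the group means correlated at -0.001 on average for equal numbers (10 of 45 pairs over 0.1) and at -0.001 for different numbers (20 of 90), and 6 of 18 libraries correlated best with their own number. With the replicate number as a block the counts were 11020, 10706, 10298 and 9364 for AAI, 36, 1816 and 2024 between genotypes, 1763 and 1473 between times, and 74 and 11 for the interactions.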

Other observations

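The values in this part come from tests fixed beforehand, except for the male-biased and female-biased lists and the values without 3 libraries, which were tests chosen only after the data were seen.

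Cytosolic ribosomal protein genes and immune cell markers other than macrophages also responded to AAI. In fl/fl at 3 weeks all 26 ribosomal protein genes rose (median 1.09, 0.65 relative to all genes, adjusted p = 0.449 with an estimated correlation), or 23 with median-of-ratios scaling. In the libraries labelled PTKO 24 rose (0.66, adjusted p = 0.536 with an estimated correlation), or 10 with that scaling. Between the genotypes at 3 weeks 17 were lower in the libraries labelled PTKO, or 21 adjusted over the list alone (-0.40, camera adjusted p = 3.15e-10, and adjusted p = 0.329 with an estimated correlation). Rplp0, of the ribosomal stalk, was at 266 ± 20.1 against 501 ± 79 CPM (-0.90, adjusted p = 0.00521), with DMSO levels of 141 ± 41.6 and 227 ± 4.41 CPM. All 16 T cell markers rose in fl/fl at 3 weeks (2.96), and 16 of 18 interferon-stimulated genes (2.61), both with an adjusted p = 0.5 with an estimated correlation. Neutrophil markers were lower in the 3-week libraries labelled PTKO in 4 of 9, or 7 adjusted over the list alone (-0.97, adjusted p = 0.329 with an estimated correlation), and complement genes in 6 of 16 by either adjustment (-0.65, adjusted p = 0.538 with an estimated correlation), with C1qa at 333 ± 130 against 867 ± 195 CPM (-1.42, adjusted p = 0.00937, a call lost without fl/fl replicate 3 or replicate 2 labelled PTKO). At 6 weeks B and plasma cell markers were lower in 5 of 8, or 6 adjusted over the list alone (-1.08, adjusted p = 0.442 with an estimated correlation), and Igj was at 303 ± 47.3 against 882 ± 45 CPM (-1.55, adjusted p = 0.0247). The Igj call was lost without replicate 1 or 3 of fl/fl or replicate 1 or 3 labelled PTKO, and both it and the list call without the 3 libraries that stood apart.

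Targets of NRF2, a transcription factor that answers oxidative stress, differed between the genotypes in both directions. At 6 weeks 5 of 18 were higher and 1 lower in the libraries labelled PTKO, or 6 and 1 adjusted over the list alone (median 0.14, camera adjusted p = 4.11e-05, and adjusted p = 0.115 with an estimated correlation). Gclc, which makes the first step of glutathione synthesis, was at 522 ± 117 against 242 ± 57.9 CPM (1.11, adjusted p = 0.00397), while the cystine transporter gene Slc7a11 was lower at 1.89 ± 0.99 against 11.9 ± 7.45 CPM (-2.06, adjusted p = 0.00387), and neither call held in a fit on the compared groups alone. At 3 weeks 6 were higher and 2 lower (0.19, camera adjusted p = 0.0423), with Nqo1 at 52.8 ± 9.02 against 22.2 ± 2.44 CPM, but that call was lost with median-of-ratios scaling, with quantile normalization, with a filter at 5 CPM, without replicate 1 or 2 of fl/fl, replicate 2 or 3 labelled PTKO or the 3 libraries that stood apart, and at adjusted p = 0.329 with an estimated correlation. Podocyte markers were lower at 6 weeks in 7 of 14, or 11 adjusted over the list alone (-0.51, camera adjusted p = 0.00032, and adjusted p = 0.236 with an estimated correlation), with the phosphatase gene Ptpro at 41 ± 5.12 against 68.5 ± 4.19 CPM. Of the Krüppel-like family, Klf6 included, 11 of 15 genes were higher and 4 lower at 3 weeks in each genotype (0.83 and 0.88, camera adjusted p = 0.652 and 0.806). Klf4 rose by 2.54 in fl/fl and 2.40 in the libraries labelled PTKO, and Klf5 by 2.69 and 2.68, while Klf15 fell by 2.08 and 1.83 and Klf12 by 1.27 and 0.70. Between the genotypes at 3 weeks Klf2 (-0.53, adjusted p = 0.0484) and Klf13 (-0.25, adjusted p = 0.0335) were lower in the libraries labelled PTKO by limma, and 0 of the 15 by edgeR. Apart from Klf6, the genes of this family were named here after their values were seen.

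The female-biased list had 3 of 7 members higher in the libraries labelled PTKO at 3 weeks (median 2.33), and 4 of 7 rose in fl/fl from 3 to 6 weeks (3.19). The male-biased list had 5 of 13 higher at 3 weeks between the genotypes (1.39) and 8 of 13 higher with 1 lower in fl/fl from 3 to 6 weeks (2.55). At 6 weeks 0 of 7 female-biased (0.33) and 1 of 13 male-biased members (-0.1) were higher in the libraries labelled PTKO than in fl/fl. From 3 to 6 weeks 0 of 7 and 2 of 13 rose in the libraries labelled PTKO (1.11 and 1.01).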
